A study of Mus musculus with 9 samples.

How the data were processed

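Gamma-delta T cells of wild-type and Il17a knockout mice had been isolated with magnetic beads and profiled by messenger RNA sequencing on a DNBSEQ instrument, after oligo(dT) enrichment and random priming. The groups were unstimulated wild-type, infected wild-type and infected Il17a knockout, with 3 libraries each and 12 h of Mycobacterium abscessus exposure in the infected groups.

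The deposited estimated counts per gene, named as read counts per the file headers, were made by the authors with a counting tool not given in the sources used here. Of their cells, 19.11% were not whole numbers. The deposited FPKM values were made by the authors from the same libraries, scaled by transcript length and by the fragments of the library. The deposited log2 fold changes and the deposited q-values came from DESeq2 per the file headers, run by the authors with settings not stated, and were used only to compare calls. The genome build was GRCm38.p6 per the submitters' processing notes. The table held 16998 genes, each of messenger RNA type, and 16947 gene identifiers were found in the RefSeq table of that build. Mitochondrially encoded genes and T cell receptor constant genes were not analysed here. How strand was used in counting is not stated.

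Estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3. The filterByExpr function kept 12816 genes and left out 4182. TMM factors, robust quasi-likelihood dispersion and a design with 1 coefficient per group were fitted to all 9 libraries, with 6 residual degrees of freedom. Each comparison used the quasi-likelihood F test, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM used TMM-scaled library sizes, and log2 CPM for principal components used a prior count of 3. Errors beside CPM are SDs over the libraries of a group.

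The 3 comparisons were infected against unstimulated wild-type, infected knockout against infected wild-type, and, as a secondary contrast, infected knockout against unstimulated wild-type. Groups, comparisons, gene lists, the naming rule and most alternatives were fixed before the data were examined. Of 36 lists fixed, 21 covered gene programs, 12 cell types and 3 quality (mitochondrially encoded, sex-linked and flanking Il17a). The 33 program and cell type lists had at least 5 tested members each and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 33 lists of a comparison. The same test with an estimated correlation and fry were run beside it. Counts of members past the threshold come from the adjustment over all genes tested, and those adjusted over the list alone stand beside them.

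Genes were named by a rule. It took 11 fixed genes (among them Il17a, Il17f, Il22, Ifng, Csf2, Tnf, Tbx21, Il23r, Il1r1 and Il1b) in every comparison. It added the 5 higher and 5 lower genes with the largest log2 fold change among those past the threshold with a mean log2 CPM of at least 3 and group values that did not overlap, without predicted models or pseudogenes. It also added the 2 members with the smallest p of each list with at least 3 members past the threshold, and members of the quality lists past the threshold. In the secondary contrast it took the fixed genes and the 2 higher and 2 lower genes with the largest change. Non-overlap of 3 against 3 libraries arises by chance in 10% of genes without a change. The mean log2 CPM was first read as the average that edgeR reports, and the reading as the mean over the 9 libraries was settled after the genes named by both had been seen. A gene outside the rule is said to be chosen after its values were seen.

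Library totals ran from 18450601 to 20374105 estimated reads, and a count of 0 allows up to 3 reads, or 0.1538 CPM in the first unstimulated library. The common biological coefficient of variation was 0.154. Replicate libraries of a group had Pearson correlations across genes of 0.9634 to 0.9898 in log2 CPM and differed by 7.89 to 41.64 in chi-square per degree of freedom, so no library was a copy of another.

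The steps were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For infected against unstimulated wild-type, 66% and 89% were recovered, with 12 false calls (7.2% of calls). For the genotypes under infection, 70% and 82% were recovered, with 11 false calls (6.7%). For the secondary contrast, 73% and 91% were recovered, with 12 false calls (6.8%). In the simulation for infected against unstimulated wild-type, camera called the changed list and 0 of 32 others, with genes simulated as independent of each other. In the real libraries, splits that mixed the groups called 13 to 18 lists for infection and 6 to 17 for the genotypes. Those splits mix the groups unevenly and keep part of the group difference, so their calls cannot be counted as false. Whether the preset correlation holds false list calls at the threshold in the real libraries was thus not measured. The list test was not run on simulated data for the other comparisons. Calls shared by comparisons that use the same libraries were set against 20 simulations without changes.

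Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, limma-trend on the deposited FPKM with pseudocounts of 1 and 0.1, no filter, at least 10 reads in 3 libraries, a fit without robust dispersion, only the 6 libraries compared, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library in turn. Counts of members per list under these alternatives, among them those without each library in turn, were added after seeing the data. A crystallin symbol list and other lens genes were listed after crystallin reads had been seen and before the other lens genes were looked at.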

Results

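Gamma-delta T cells are lymphocytes whose antigen receptor is built from a gamma and a delta chain, and part of them make the cytokine IL-17A. RNA sequencing measured messenger RNA in such cells, isolated with magnetic beads from wild-type mice or from mice lacking Il17a. The 9 libraries fell into 3 groups of 3: unstimulated wild-type cells, wild-type cells exposed for 12 h to Mycobacterium abscessus, and Il17a knockout cells exposed in the same way. M. abscessus is a fast-growing nontuberculous mycobacterium. The groups held no unstimulated knockout cells, so the genotypes were compared under infection only, and the time unstimulated cells spent in culture was not stated. The titles of the samples carry the word muscle.

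Library totals were 19508032, 19537368 and 18748190 estimated reads in the unstimulated wild-type group. They were 20374105, 20318679 and 19643834 in the infected wild-type group, and 18950854, 19721654 and 18450601 in the infected knockout group. Between 14414 and 14989 genes had at least 1 read in 8 of the libraries, and 13063 in infected knockout replicate 3. That library also stood apart within its group on principal component 2, at 20.2 against 2.7 and -3.3. The first 2 components held 63.3% and 17.2% of the variance. Whether replicates came from separate mice or separate cultures is not given, and the p-values below measure only the spread between libraries of such unknown origin. A library count of 0 allows up to 3 reads, which covers counting error only.

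Il17a (gene 16171, chromosome 1, 20730905 to 20734496, GRCm38.p6), which encodes IL-17A, had 85, 62 and 62 reads in the unstimulated wild-type libraries. It had 14237, 14264 and 12661 reads in the infected wild-type libraries and 28, 35 and 10 in the infected knockout libraries. The counts are per gene, and where in the gene the remaining knockout reads lie was not analysed here.

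The comparison of infected with unstimulated wild-type cells asked which genes respond to the mycobacterium. Il17a rose 197-fold, from 3.42 ± 0.572 to 677 ± 47.9 CPM (read counts scaled by library size; SD, n = 3 libraries per group here and below), a log2 fold change of 7.62 ± 0.21 (SE; adjusted p = 5.41e-11). Il17f (gene 257630, chromosome 1, 20777146 to 20785274), which encodes the related cytokine IL-17F, rose 79.1-fold to 111 ± 13.9 CPM, by 6.31 ± 0.23 (adjusted p = 7.85e-10). Il22, whose cytokine acts on epithelial barriers, rose from 0.599 ± 0.37 to 11.7 ± 1.21 CPM, by 4.28 ± 0.40, and Csf2, which encodes the growth factor GM-CSF, rose 8.53-fold, by 3.09 ± 0.17. Neutrophil granule genes and Apoe, a lipid carrier made by macrophages, fell, with log2 fold changes of -3.55 ± 0.46 for Ltf, -3.08 ± 0.29 for Camp, -2.90 ± 0.24 for Ngp and -3.51 ± 0.13 for Apoe.

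Of 12816 genes tested, 3288 changed in that comparison, 1822 higher and 1466 lower, and 948 of them by a log2 fold change of at least 1. Il1b, which encodes the inflammatory cytokine IL-1 beta, rose by 3.56 ± 0.25, Tnf by 0.88 ± 0.13 and Il1r1, the signalling receptor for IL-1, by 0.55 ± 0.11. The genes with the largest rises by the naming rule also held Cxcl2, a chemokine that attracts neutrophils, at 7.0 ± 0.24 (128-fold), Il1r2, a decoy receptor for IL-1, at 4.31 ± 0.27, and Tnfrsf9, a co-stimulatory receptor of activated T cells, at 4.15 ± 0.15. Slc40a1, the iron exporter ferroportin, fell by 2.81 ± 0.26. Ifng, the gene of interferon-gamma, rose by 1.66 ± 0.47 (adjusted p = 0.0182), from 2.11 ± 0.98 to 6.69 ± 0.731 CPM. That call ended without unstimulated replicate 1 (1.47, adjusted p = 0.0706) or 3 (1.51, adjusted p = 0.0672), and without infected wild-type replicate 1 (1.65, adjusted p = 0.0661) or 2 (1.60, adjusted p = 0.0832), and over its 17 alternatives the adjusted p ran from 0.000528 to 0.0832. Tbx21, the lineage transcription factor of type 1 cells (-0.05 ± 0.18, adjusted p = 0.885), did not pass, nor did Il23r, a chain of the IL-23 receptor (0.05 ± 0.14, adjusted p = 0.848). With upper-quartile factors the share of changed genes that were higher was 45.2% in place of 55.4%. Without infected wild-type replicate 2 the number of changed genes was 2026.

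**Figure D1:**
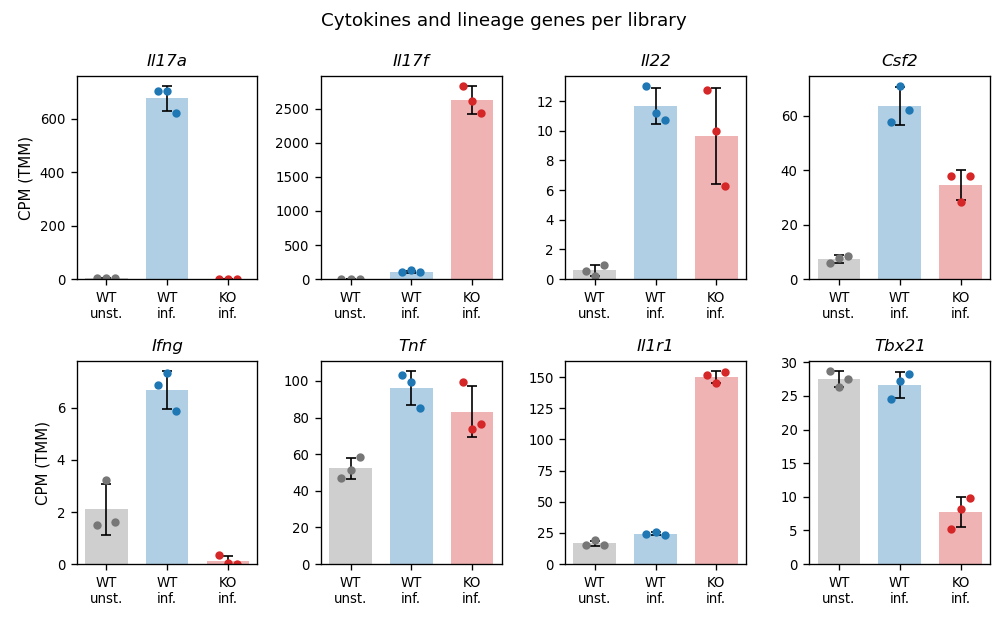
CPM (y axis, from 0) of 8 cytokine, receptor and transcription factor genes in the 3 groups (x axis), with bars at the mean of 3 libraries, error bars of 1 SD and points for single libraries. Il17a is high in infected wild-type libraries alone, at 677 CPM, and Il17f reaches 2628 CPM in infected knockout libraries.

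Of 33 gene lists fixed before the data were examined and tested as groups, 19 were called in infected against unstimulated wild-type cells, 13 toward higher and 6 toward lower values. With a correlation between genes estimated for each list, 14 of the 19 calls held. In a fit of only the 6 libraries compared, 19 were called and 11 held. Splits of the 6 libraries that mixed the groups still called 13 to 18 lists at the preset correlation. Such splits mix the groups unevenly and keep part of the group difference, so how many lists would be called without it was not measured. Type 17 cytokine and lineage genes numbered 14 higher, 3 lower and 6 not passed of 23 (14 and 3 adjusted over the list alone; list adjusted p = 1.26e-16), and Il17a, Il17f, Il22 and Csf2 were among those that rose. The 3 lower members, named after their values were seen, were Sox4, Serpinb1a and Il18r1. T cell activation genes numbered 12 higher, 1 lower and 10 not passed of 23 (12 and 1 adjusted over the list alone; list adjusted p = 1.42e-14), with Il2ra, a chain of the IL-2 receptor, at 2.19 ± 0.12. The lower member, Egr2, was named after its value was seen, and did not pass without unstimulated replicate 1 or infected wild-type replicate 2 or 3. Quiescence and lymphoid homing genes fell in 13 of 20 cases and rose in 0 (13 lower adjusted over the list alone; list adjusted p = 0.000132), including the IL-7 receptor gene Il7r at -0.82 ± 0.11 and the homing receptor gene Ccr9 at -0.58 ± 0.10. Type 1 and cytotoxic genes numbered 6 higher, 8 lower and 9 not passed of 23 (6 and 9 adjusted over the list alone), with the granule protease gene Gzmb at 2.02 ± 0.20 and the chemokine receptor gene Cxcr3 at -0.78 ± 0.10. That list was not called (adjusted p = 0.562).

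Among myeloid inflammatory cytokines and mediators, 21 of 24 rose, 1 fell and 2 did not pass (22 and 1 adjusted over the list alone; list adjusted p = 5.03e-34), while markers of macrophages and monocytes fell (17 of 20 lower). Their median log2 fold change was 3.46, or 3.29 with the 2 genes absent from a group set at their bound. Cxcl2 and Il1b belonged to that list, as did Ccl3, a chemokine for monocytes and T cells, at 3.71 ± 0.19, and the lower member Lcn2 was named after its value was seen. NF-kB target and feedback genes rose in 21 of 22 cases and fell in 0 (21 higher adjusted over the list alone; list adjusted p = 4.9e-19), with the activation marker Cd83 at 1.98 ± 0.09 and the NF-kB inhibitor gene Nfkbib at 1.20 ± 0.09. Interferon-gamma inducible GTPases and related genes numbered 17 higher, 0 lower and 5 not passed of 22 (18 higher adjusted over the list alone; list adjusted p = 5.29e-08). Its members of smallest p were the GTPase genes Tgtp1 (1.27 ± 0.12) and Tgtp2 (0.98 ± 0.09), near-identical copies that can exchange reads.

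Type I interferon response genes were not called (adjusted p = 0.816): 3 of 27 rose, 0 fell and 24 did not pass (2 higher adjusted over the list alone). Among them were Bst2, an antiviral membrane protein, at 0.50 ± 0.14, and Isg15, named after its value was seen. The number was 1 without unstimulated replicate 1, infected wild-type replicate 1 or infected wild-type replicate 2, and Bst2 then had an adjusted p of 0.0643, 0.0884 and 0.0555, within a range of 0.00304 to 0.0884 over 17 alternatives. IL-1 and IL-23 receptor signalling genes numbered 7 higher, 0 lower and 16 not passed of 23 (7 adjusted over the list alone; list adjusted p = 0.00935), with the receptor chain gene Il12rb1 at 0.93 ± 0.09. The call was lost, at adjusted p = 0.239 with an estimated correlation. IL-17 receptor signalling and target genes numbered 7 higher, 7 lower and 4 not passed of 18 (7 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.12). Cxcl1, a chemokine gene of that list, had 1 read in the 3 unstimulated libraries and 637 in the infected wild-type libraries. Pattern recognition receptors and adaptors numbered 6 higher, 6 lower and 14 not passed of 26 (6 and 7 adjusted over the list alone; list adjusted p = 0.856), with the mycobacterial glycolipid receptor gene Clec4e at 2.33 ± 0.24 and Cd14 at 1.57 ± 0.13. The lower count there was 3 without unstimulated replicate 1 or infected wild-type replicate 2. MHC class II antigen presentation genes numbered 5 higher, 1 lower and 10 not passed of 16 (6 and 2 adjusted over the list alone; list adjusted p = 0.237), with the invariant chain gene Cd74 at 0.75 ± 0.08 and H2-Ab1 at 1.04 ± 0.14. The lower count there was 3 without knockout replicate 3, and 0 without unstimulated replicate 2 or 3 or infected wild-type replicate 2.

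Glycolysis and hypoxia genes rose in 23 of 25 cases and fell in 0 (24 higher adjusted over the list alone; list adjusted p = 1.01e-56), including Tpi1, a glycolytic enzyme, at 3.17 ± 0.12 and Slc16a3, a lactate exporter, at 3.46 ± 0.15. Cholesterol synthesis genes rose in 18 of 21 cases and fell in 0 (20 higher adjusted over the list alone; list adjusted p = 3.53e-27), with Idi1 at 3.38 ± 0.19 and Cyp51 at 2.02 ± 0.11, both enzymes of that pathway. Ribosome biogenesis genes rose in 25 of 28 cases and fell in 0 (26 higher adjusted over the list alone; list adjusted p = 5.06e-17), with the small nucleolar RNA-binding genes Nhp2 at 1.22 ± 0.11 and Fbl at 0.86 ± 0.08. Amino acid and unfolded protein stress genes numbered 16 higher, 1 lower and 7 not passed of 24 (17 and 1 adjusted over the list alone; list adjusted p = 5.85e-18), with the asparagine synthesis gene Asns at 2.10 ± 0.09 and the serine synthesis gene Psat1 at 2.72 ± 0.13. Genes of the p53 and apoptosis list numbered 13 higher, 3 lower and 7 not passed of 23 (14 and 3 adjusted over the list alone; list adjusted p = 5.29e-08), with the growth arrest genes Gadd45b at 2.47 ± 0.11 and Cdkn1a at 2.14 ± 0.13. The lower count there was 1 without infected wild-type replicate 3.

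Heat shock genes numbered 9 higher, 1 lower and 8 not passed of 18 (10 and 1 adjusted over the list alone; list adjusted p = 9.86e-05), with the chaperone genes Hspd1 at 1.23 ± 0.10 and Hsph1 at 1.29 ± 0.12. That call was lost, at adjusted p = 0.0688 with an estimated correlation, and the lower member, the crystallin gene Cryab, was named after its value was seen. Oxidative phosphorylation genes numbered 7 higher, 0 lower and 21 not passed of 28 (10 higher adjusted over the list alone; list adjusted p = 0.00935), with the respiratory chain genes Cycs at 1.22 ± 0.14 and Uqcrq at 0.95 ± 0.14. The call was lost, at adjusted p = 0.375 with an estimated correlation, and the count of higher genes was 4 without infected wild-type replicate 1, 11 without knockout replicate 2 and 12 without knockout replicate 3. Oxidative stress and metallothionein genes numbered 6 higher, 5 lower and 8 not passed of 19 (7 and 6 adjusted over the list alone; list adjusted p = 0.316), with the cystine transporter gene Slc7a11 at 2.16 ± 0.14 and the antioxidant gene Srxn1 at 1.01 ± 0.10. Cell cycle genes numbered 3 higher, 5 lower and 24 not passed of 32 (3 and 5 adjusted over the list alone; list adjusted p = 0.126), with Top2a at 0.64 ± 0.14 and the replication licensing gene Cdt1 at -0.49 ± 0.11. The lower count was 2 without unstimulated replicate 2 and 1 without infected wild-type replicate 2.

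Markers of several other blood cells fell after infection. Macrophage and monocyte markers fell in 17 of 20 cases and rose in 0 (18 lower adjusted over the list alone; list adjusted p = 3.29e-18). The lysozyme gene Lyz2 went from 331 ± 65.9 to 56.5 ± 4.59 CPM, a fall by 2.55 ± 0.14, and Cd5l, which tissue macrophages secrete, fell by 2.89 ± 0.20. Neutrophil markers numbered 1 higher, 13 lower and 6 not passed of 20 (1 and 14 adjusted over the list alone; list adjusted p = 2.41e-10), with Retnlg at -4.26 ± 0.31, and Il1r2 was the member that rose. Erythroid markers numbered 1 higher, 7 lower and 3 not passed of 11 (1 and 8 adjusted over the list alone; list adjusted p = 0.00076). Their alpha globin gene Hba-a2, which has an identical copy in Hba-a1, fell by 1.38 ± 0.12, and the transferrin receptor gene Tfrc, also made by dividing T cells, rose by 2.12 ± 0.14. B cell markers fell in 5 of 9 cases and rose in 0 (5 lower adjusted over the list alone; list adjusted p = 0.0238), with Blnk at -1.63 ± 0.34 and Pou2af1 at -0.78 ± 0.17. That call was lost, at adjusted p = 0.0809 with an estimated correlation, and the count was 3 without any 1 of 6 libraries: unstimulated replicates 1, 2 and 3, infected wild-type replicates 1 and 3, and knockout replicate 1. NK cell markers fell in 3 of 13 cases and rose in 0 (3 lower adjusted over the list alone; list adjusted p = 0.0243), with Klrb1f at -1.43 ± 0.21 and Gzma at -0.96 ± 0.22. That call was lost too, at adjusted p = 0.0809 with an estimated correlation.

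The lists of other cell types were not called in infected against unstimulated wild-type cells. Gamma-delta T cell markers numbered 2 higher, 0 lower and 7 not passed of 9 (2 adjusted over the list alone; list adjusted p = 0.739), and alpha-beta T cell markers 0 higher, 2 lower and 8 not passed of 10 (2 adjusted over the list alone; list adjusted p = 0.289). Named after their values were seen, these were Blk and Zbtb16 among the former and Cd28 and Trat1 among the latter. The alpha-beta count was 1 without unstimulated replicate 2 or 3 or infected wild-type replicate 2 or 3. Dendritic cell markers numbered 1 higher, 2 lower and 12 not passed of 15 (1 and 2 adjusted over the list alone; list adjusted p = 0.549). The integrin gene Itgax among them fell by 1.75 ± 0.45, a call that ended without unstimulated replicate 2 (-1.62, adjusted p = 0.0525, the highest of 17 alternatives that started at 0.0012) and left 0 dendritic cell markers lower. Megakaryocyte markers numbered 1 lower and 5 not passed of 6 (1 adjusted over the list alone; list adjusted p = 0.316), and fibroblast and endothelial markers 2 higher and 7 not passed of 9 (2 adjusted over the list alone; list adjusted p = 0.124). Of 5 mast cell markers (list adjusted p = 0.83), 0 passed with edgeR, 1 had an unadjusted p under 0.05, and 1 passed with DESeq2 and 1 with limma-voom. Of 5 skeletal muscle markers (list adjusted p = 0.827), 0 passed with edgeR, 2 had an unadjusted p under 0.05, and 0 passed with DESeq2 and 1 with limma-voom. Median, mean and test differed in sign for some uncalled lists. The type 1 list had a median of -0.23 and a mean of 0.16 with a test toward lower. The IL-17 receptor (-0.02 and 1.56), gamma-delta T cell (-0.01 and 0.08) and fibroblast (-0.01 and 0.82) lists had a negative median, a positive mean and a test toward higher, and the mast cell list had both negative (-0.12 and -0.49) with a test toward higher.

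**Figure D2:**
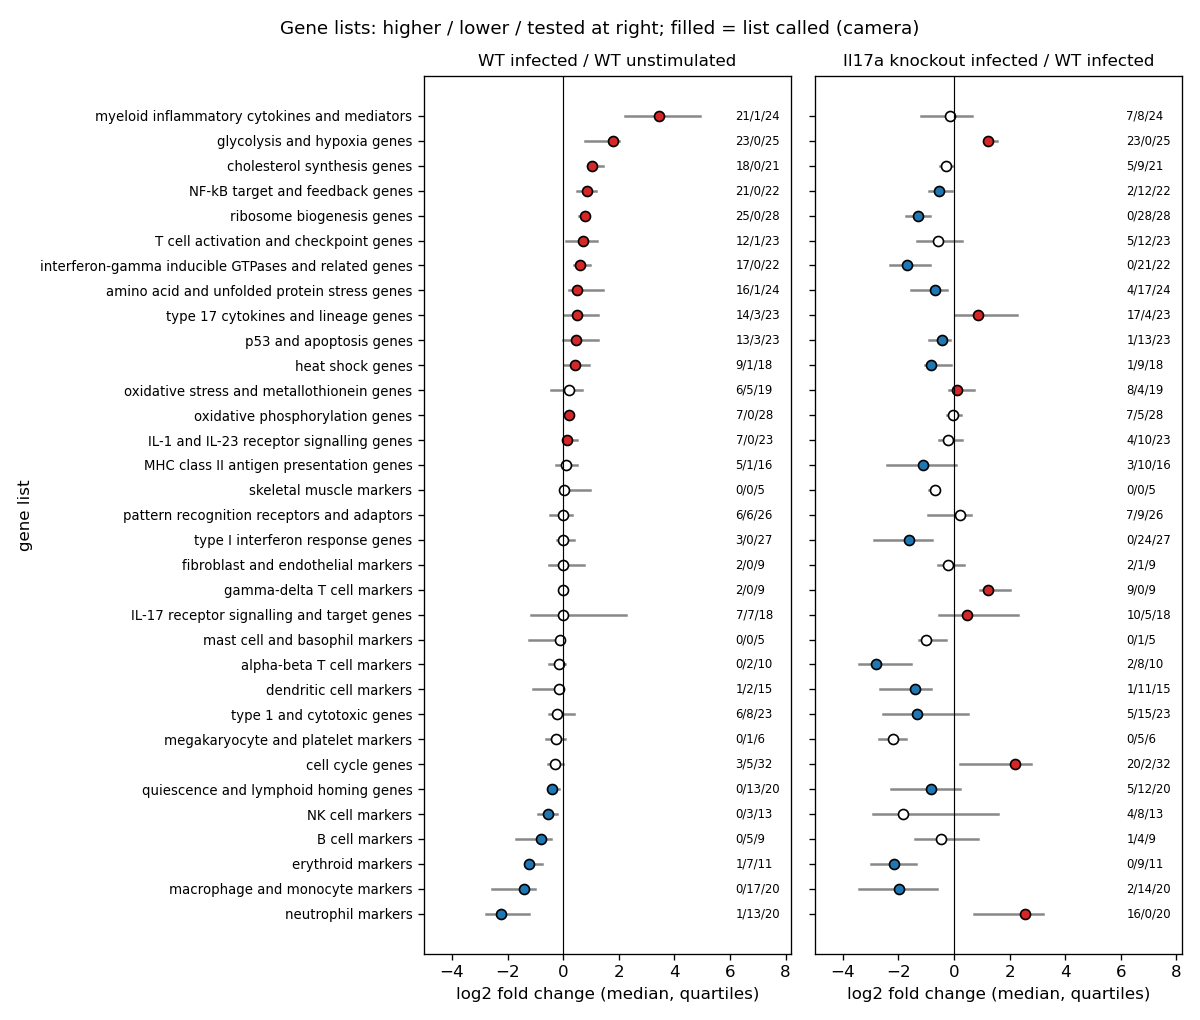
Median (points) and quartiles (lines) of the log2 fold change (x axis) of the tested members of 33 gene lists (y axis), for infected against unstimulated wild-type cells and for infected knockout against infected wild-type cells, with the members higher, lower and tested at the right. Filled points mark called lists, red for higher and blue for lower, and the interferon-gamma GTPase list lies at 0.59 in the first panel and -1.70 in the second.

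The comparison of infected knockout with infected wild-type cells asked how cells lacking Il17a differ under infection. Il17a was 496-fold lower in the knockout, at 1.35 ± 0.691 against 677 ± 47.9 CPM (log2 fold change -8.95 ± 0.23, adjusted p = 6.32e-12). Its neighbour Il17f was 23.6-fold higher, at 2628 ± 202 against 111 ± 13.9 CPM (4.56 ± 0.18, adjusted p = 3.86e-10), and reached at least 2435 CPM in each of the 3 knockout libraries. Il1r1 was higher by 2.62 ± 0.11, from 24.4 ± 1.15 to 150 ± 4.82 CPM. Ifng fell by 5.61 ± 0.65, with 7 reads in the 3 knockout libraries against 407 in the infected wild-type libraries, and Tbx21 fell by 1.78 ± 0.19.

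Between the genotypes 6300 of the 12816 genes changed, 2961 higher and 3339 lower in the knockout, and 2738 of them by a log2 fold change of at least 1. Among the genes with the largest rises by the naming rule were Ccr10, a chemokine receptor of skin-homing cells, at 6.06 ± 0.29, the metallothionein gene Mt1 at 4.86 ± 0.18, the unconventional myosin gene Myo16 at 4.95 ± 0.25 and the crystallin gene Cryba4 at 4.91 ± 0.35. Tgtp1 fell by 6.90 ± 0.17, from 165 ± 10 to 1.38 ± 0.443 CPM, as did Ccl22, a chemokine that attracts T cells (-4.98 ± 0.30), Tdrp (-4.9 ± 0.37) and the transcription factor gene Pou6f1 (-4.70 ± 0.30). Csf2 fell by 0.88 ± 0.16 and Il23r rose by 0.54 ± 0.14. Il22 (-0.27 ± 0.31, adjusted p = 0.491) and Tnf (-0.21 ± 0.13, adjusted p = 0.203) did not pass. Il1b fell by 0.65 ± 0.21 (adjusted p = 0.0213), a call that ended without infected wild-type replicate 1 (-0.50, adjusted p = 0.108) or 2 (-0.51, adjusted p = 0.109) or knockout replicate 2 (-0.58, adjusted p = 0.06). Over its 17 alternatives the adjusted p ran from 0.000593 to 0.109. On the deposited FPKM the share of changed genes that were higher was 36.7%, or 35.7% with a pseudocount of 0.1, in place of 47%. The median of all genes then stood at -0.118, or at -0.169 with the smaller pseudocount, in place of -0.042.

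Between the genotypes 21 of 33 lists were called, 7 toward higher and 14 toward lower values in the knockout, and 15 held with an estimated correlation. In a fit of only the 6 libraries compared, 21 were called and 6 held. Splits of those 6 libraries that mixed the groups called 6 to 17 lists at the preset correlation. Type 17 genes numbered 17 higher, 4 lower and 2 not passed of 23 (17 and 4 adjusted over the list alone; list adjusted p = 6.28e-09), with the leukotriene receptor gene Ltb4r1 at 3.46 ± 0.10. Their lower members were Il17a, Csf2 and, named after their values were seen, Sox4 and Ahr. Gamma-delta T cell markers rose in 9 of 9 cases (9 adjusted over the list alone; list adjusted p = 9.48e-14), with the kinase gene Blk at 2.57 ± 0.11 and Zbtb16, the transcription factor PLZF, at 2.01 ± 0.09. No gamma or delta receptor gene of that list was analysed. Cd3d, Cd3e, Cd3g and Cd247, which are not particular to gamma-delta T cells, were among its tested members. The other tested members, Blk and Zbtb16 included, also belonged to the type 17 list. Alpha-beta T cell markers numbered 2 higher and 8 lower of 10 (2 and 8 adjusted over the list alone; list adjusted p = 8.52e-06): the co-receptor gene Cd4 fell by 4.48 ± 0.33, from 8.05 ± 0.849 to 0.352 ± 0.156 CPM, and the co-stimulatory receptor gene Cd28 by 2.75 ± 0.12. Its higher members, Cd5 and Cd6, were named after their values were seen, and 1 of them passed without infected wild-type replicate 1. Type 1 and cytotoxic genes numbered 5 higher, 15 lower and 3 not passed of 23 (6 and 15 adjusted over the list alone; list adjusted p = 5.27e-05), with Cxcr3 at -3.93 ± 0.12 and the chemokine gene Ccl5 at -3.41 ± 0.11. The 5 higher members, named after their values were seen, were Gzma, Gzmb, Prf1, Klrk1 and Il18rap, of which the first 3 encode proteins of cytotoxic granules. Quiescence and lymphoid homing genes numbered 5 higher, 12 lower and 3 not passed of 20 (5 and 13 adjusted over the list alone; list adjusted p = 1.46e-10), with the homing receptor genes Ccr9 at -4.08 ± 0.12 and Ccr7 at -3.47 ± 0.10. Without infected wild-type replicate 2 the higher count was 3.

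In the knockout, interferon-gamma inducible GTPases and related genes fell in 21 of 22 cases and rose in 0 (21 lower adjusted over the list alone; list adjusted p = 2.46e-23), with Tgtp1 and Tgtp2 (-4.21 ± 0.11) the members of smallest p. Type I interferon response genes fell in 24 of 27 cases and rose in 0 (24 lower adjusted over the list alone; list adjusted p = 7.08e-09), with Ddx58, the RNA sensor RIG-I, at -1.60 ± 0.13. The call was lost, at adjusted p = 0.0504 with an estimated correlation. MHC class II antigen presentation genes numbered 3 higher, 10 lower and 3 not passed of 16 (3 and 11 adjusted over the list alone; list adjusted p = 6.73e-05), with H2-Aa at -3.04 ± 0.11 and Cd74 at -2.37 ± 0.09. Markers of dendritic cells (11 of 15) and macrophages (14 of 20), cells that bear class II, fell alongside. NF-kB target and feedback genes numbered 2 higher, 12 lower and 8 not passed of 22 (2 and 14 adjusted over the list alone; list adjusted p = 0.000359), with Cd83 at -2.98 ± 0.10 and the adaptor gene Traf1 at -1.49 ± 0.09. The higher count was 4 without knockout replicate 2 and 1 without infected wild-type replicate 1. IL-17 receptor signalling and target genes numbered 10 higher, 5 lower and 3 not passed of 18 (10 and 5 adjusted over the list alone; list adjusted p = 0.00523), with the neutrophil proteins S100a8 at 3.74 ± 0.20 and S100a9 at 3.20 ± 0.25, while neutrophil markers rose. That call was lost, at adjusted p = 0.0502 with an estimated correlation.

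Cell cycle genes rose in 20 of 32 cases and fell in 2 (20 and 2 adjusted over the list alone; list adjusted p = 9.02e-11). Mki67, a marker of dividing cells, went from 13.8 ± 1.55 to 181 ± 5.16 CPM, a rise of 3.71 ± 0.16, and Ube2c, which acts in mitosis, rose by 3.31 ± 0.19. The lower count was 1 without infected wild-type replicate 3 or knockout replicate 1. Glycolysis and hypoxia genes rose in 23 of 25 cases and fell in 0 (23 higher adjusted over the list alone; list adjusted p = 1.14e-21), with the aldolase gene Aldoc at 3.70 ± 0.18 and Egln3, an oxygen-sensing hydroxylase, at 2.50 ± 0.12. Oxidative stress and metallothionein genes numbered 8 higher, 4 lower and 7 not passed of 19 (8 and 4 adjusted over the list alone; list adjusted p = 0.0174), with Mt2 at 4.97 ± 0.26 beside Mt1. That call was lost, at adjusted p = 0.247 with an estimated correlation. The higher count was 5 without infected wild-type replicate 2 and the lower count 2 without infected wild-type replicate 1. Ribosome biogenesis genes fell in 28 of 28 cases (28 adjusted over the list alone; list adjusted p = 6.26e-18), with Nop56 at -1.76 ± 0.10 and Fbl at -1.35 ± 0.08. Amino acid and unfolded protein stress genes numbered 4 higher, 17 lower and 3 not passed of 24 (4 and 18 adjusted over the list alone; list adjusted p = 6.85e-07), with the serine and glycine pathway genes Phgdh at -2.28 ± 0.09 and Shmt2 at -2.20 ± 0.10. Heat shock genes numbered 1 higher, 9 lower and 8 not passed of 18 (1 and 9 adjusted over the list alone; list adjusted p = 0.00416), with Hspd1 at -1.65 ± 0.10 and the heat shock factor gene Hsf1 at -1.08 ± 0.10. That call was lost, at adjusted p = 0.152 with an estimated correlation. Genes of the p53 and apoptosis list numbered 1 higher, 13 lower and 9 not passed of 23 (1 and 13 adjusted over the list alone; list adjusted p = 0.000524), with the survival gene Bcl2 at -3.93 ± 0.23 and the death receptor gene Fas at -2.36 ± 0.16.

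Markers of other blood cells moved in different directions between the genotypes. Neutrophil markers rose in 16 of 20 cases and fell in 0 (16 higher adjusted over the list alone; list adjusted p = 5.55e-07), with S100a8 going from 64.5 ± 10.7 to 865 ± 145 CPM. The same list had fallen after infection in wild-type cells, with a median log2 fold change of -2.23. Between infected knockout and unstimulated wild-type cells it was not called, at 7 higher, 5 lower and 8 not passed (7 and 7 adjusted over the list alone; list adjusted p = 0.382). Erythroid markers fell in 9 of 11 cases and rose in 0 (9 lower adjusted over the list alone; list adjusted p = 1.45e-06), with Hba-a2 at -2.14 ± 0.13 and the carbonic anhydrase gene Car2 at -3.38 ± 0.23. Macrophage and monocyte markers numbered 2 higher, 14 lower and 4 not passed of 20 (2 and 14 adjusted over the list alone; list adjusted p = 0.000716), with the monocyte surface gene Ly6c2 at -3.42 ± 0.18 and the chemokine receptor gene Ccr2 at 2.02 ± 0.10. Dendritic cell markers numbered 1 higher, 11 lower and 3 not passed of 15 (1 and 11 adjusted over the list alone; list adjusted p = 0.00323), with the chemokine receptor genes Ccr7 lower and Xcr1 higher, at 1.76 ± 0.13. The macrophage call was lost, at adjusted p = 0.197 with an estimated correlation, as was the dendritic cell call, at adjusted p = 0.0898 with an estimated correlation.

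The remaining lists were not called between the genotypes. T cell activation genes numbered 5 higher, 12 lower and 6 not passed of 23 (6 and 12 adjusted over the list alone; list adjusted p = 0.479), with the early response gene Egr1 at 3.01 ± 0.13 and Myc, which drives cell growth, at -2.27 ± 0.14. Myeloid inflammatory cytokines numbered 7 higher, 8 lower and 9 not passed of 24 (7 and 8 adjusted over the list alone; list adjusted p = 0.859), with Lcn2, an iron-sequestering protein of neutrophils, at 3.84 ± 0.21. Pattern recognition genes numbered 7 higher, 9 lower and 10 not passed of 26 (8 and 9 adjusted over the list alone; list adjusted p = 0.746), with the inflammasome adaptor gene Pycard at 2.02 ± 0.12 and the signalling inhibitor gene Irak3 at 1.42 ± 0.08. IL-1 and IL-23 receptor signalling genes numbered 4 higher, 10 lower and 9 not passed of 23 (5 and 11 adjusted over the list alone; list adjusted p = 0.658), with the signalling inhibitor gene Socs3 at -1.25 ± 0.15. Cholesterol synthesis genes numbered 5 higher, 9 lower and 7 not passed of 21 (5 and 9 adjusted over the list alone; list adjusted p = 0.533), with Idi1 at -1.61 ± 0.17 and the regulator gene Srebf2 at 0.61 ± 0.08. Oxidative phosphorylation genes numbered 7 higher, 5 lower and 16 not passed of 28 (7 and 5 adjusted over the list alone; list adjusted p = 0.759), with Ndufa1 at 1.17 ± 0.15 and Cox5b at 0.63 ± 0.10. The lower count there was 3 without infected wild-type replicate 1 and 2 without knockout replicate 1 or 3.

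Among uncalled cell type lists, NK cell markers numbered 4 higher, 8 lower and 1 not passed of 13 (4 and 9 adjusted over the list alone; list adjusted p = 0.35), with Klrb1f at 2.78 ± 0.22 and Klrb1c, the NK1.1 antigen, at -2.30 ± 0.18. B cell markers numbered 1 higher, 4 lower and 4 not passed of 9 (2 and 4 adjusted over the list alone; list adjusted p = 0.908), with the B cell receptor chain gene Cd79b at 2.71 ± 0.14 and Spib, with 15 reads in the knockout libraries, at -3.80 ± 0.56. Megakaryocyte markers numbered 5 lower and 1 not passed of 6 (1 higher and 5 lower adjusted over the list alone; list adjusted p = 0.23), with the platelet integrin gene Itga2b at -1.85 ± 0.35, and the platelet factor gene Pf4 had 2 reads in the knockout against 90 in infected wild-type libraries. That lower count was 3 without infected wild-type replicate 2 or knockout replicate 2. Fibroblast and endothelial markers numbered 2 higher, 1 lower and 6 not passed of 9 (2 and 1 adjusted over the list alone; list adjusted p = 0.908), with the endothelial cadherin gene Cdh5 at 6.23 ± 0.60 and the matrix gene Lum at -4.76 ± 0.35. Mast cell markers numbered 1 lower of 5 (1 adjusted over the list alone; list adjusted p = 0.143). Of 5 skeletal muscle markers (list adjusted p = 0.682), 0 passed with edgeR, 1 had an unadjusted p under 0.05, and 0 passed with DESeq2 and 0 with limma-voom. The myeloid cytokine (median -0.15, mean -0.23) and B cell (median -0.47, mean -0.39) lists had a test toward higher, as did the pattern recognition (median 0.20, mean -0.18) and oxidative phosphorylation (median -0.05, mean 0.04) lists.

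**Figure D3:**
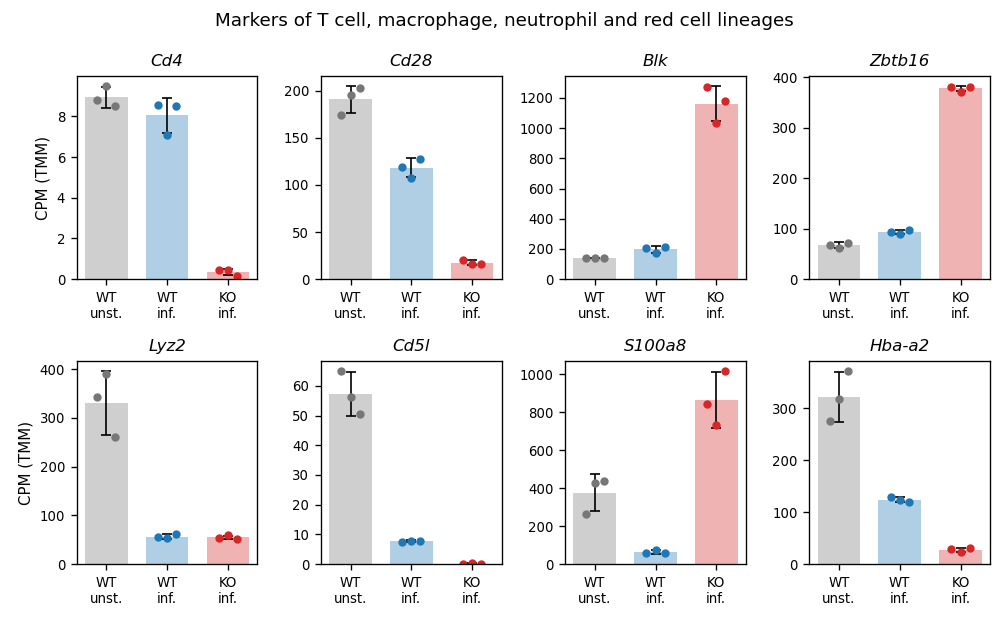
CPM (y axis, from 0) of 8 cell type markers in the 3 groups (x axis), with bars at the mean of 3 libraries, error bars of 1 SD and points for single libraries. Cd4 falls to 0.352 CPM and Blk reaches 1162 CPM in infected knockout libraries, while Lyz2 is highest in unstimulated libraries at 331 CPM.

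Genes changed by infection in wild-type cells were set against those that differed between the genotypes. Of the 2156 genes changed in both comparisons, 1336 moved in opposite directions and 820 in the same direction. Infection raised 797 genes that were lower in the knockout, such as Tgtp1, Cd83 and Fbl, and 424 that were higher there, such as Il17f. Infection lowered 539 genes that were higher in the knockout, such as Klrb1f and S100a8, the latter at -2.55 after infection and chosen for that value after it was seen. It lowered 396 genes that were also lower in the knockout, such as Ccr9. Independent lists of these sizes would share 475, 421, 339 and 382 genes in the same order. Both comparisons use the infected wild-type libraries with opposite signs, so chance alone favours opposite directions: the correlation of log2 fold changes across genes, which are not independent replicates, was -0.049, against -0.5 in 20 simulations without changes, and their covariance was -0.05, against -0.052. The simulations held no changed genes, so the at most 0 genes called in both comparisons there are no baseline for the 2156 here. Independent lists would share 1617 in all. The part of the shared libraries in the 1336 was not measured. Without infected wild-type replicate 2 the shared number was 1292.

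Infected knockout and unstimulated wild-type cells differed in both genotype and infection, and were compared as a secondary contrast. Il17f was 1870-fold higher in the infected knockout (10.87 ± 0.26, adjusted p = 3.57e-12) and Cxcl2 285-fold (8.15 ± 0.25), while Apoe was 64.7-fold lower, at 4.34 ± 0.568 against 281 ± 16.1 CPM, and Tgtp1 49.5-fold lower. Il17a stood below its unstimulated wild-type level, by -1.33 ± 0.27 (adjusted p = 0.00091), and Ifng fell by 3.95 ± 0.67. Il1r1 (3.17 ± 0.12), Il1b (2.91 ± 0.24), Il22 (4.01 ± 0.40), Csf2 (2.22 ± 0.17), Tnf (0.67 ± 0.13) and Il23r (0.58 ± 0.14) rose, and Tbx21 fell by 1.83 ± 0.19. In all, 6657 genes changed, 3294 higher and 3363 lower. On the deposited FPKM the share that was higher was 35.5%, or 35.2% with a pseudocount of 0.1, in place of 49.5%, and the median of all genes stood at -0.148 or -0.201 in place of -0.025. Of the genes that infection raised in wild-type cells, 1019 of 1822 were also higher in the infected knockout, and 836 of the 1466 that it lowered were also lower, where independent lists of these sizes would share 468 and 385. The unstimulated libraries are shared by both contrasts, and the correlation of log2 fold changes across genes was 0.505, against 0.497 in simulations without changes. Their covariance was 0.603, against 0.051 in the simulations.

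The authors' deposited table calls 4403 genes at a q-value under 0.05 between infected and unstimulated wild-type cells, and 3259 of the 3288 genes called here were among them. For the genotypes under infection the authors' deposited table calls 6034 genes, which held 5854 of the 6300 called here. Each shared gene had the same direction in the authors' deposited table as here.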

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

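The alternatives were planned, apart from counts of members per list, among them those without each library in turn, which were tests chosen after seeing the data. Of 172 named gene results, all but 19 kept direction and side of the threshold under each of the 17 alternatives run for named genes. The fits on the deposited FPKM and the fit without robust dispersion were not among these 17, so named genes were not checked there. The 19 results gave 76 values that no longer passed, 1 that newly passed and 2 of opposite sign. The opposite signs were Tbx21 (0.01 without infected wild-type replicate 1, range -0.09 to 0.01 over left-out libraries) and Il23r (-0.02 with upper-quartile factors), both in infected against unstimulated wild-type and never past the threshold. Requiring a log2 fold change of at least 1 left 948, 2738 and 3039 genes in the infection, genotype and secondary comparisons, by construction of a stricter limit. Leaving out 1 library at a time gave 2026 to 4150, 5191 to 6556 and 5715 to 6739 genes, and 1292 to 2582 genes changed in both infection and genotype comparisons. The lowest values for infection and for both came without infected wild-type replicate 2, the highest without knockout replicate 3, and the cause was not tested. Called lists ran from 19 to 20 and 21 to 22. With fry, which does not compare a list with other genes, 31 and 33 lists changed in either direction. The replicate number as a block (replicate block) gave 2977, 6045 and 6437 genes, 20 and 21 lists and 1963 shared genes. Replicate numbers did not pair libraries, with correlations of -0.078 to 0.072. B cell markers lower after infection numbered 3 in place of 5 without unstimulated replicate 3. At 18450601 or more reads, genes under the filter were not tested.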

Other observations

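The lens gene test and the splits of the libraries were planned before their results were seen, and the other tests, with the splits at an estimated correlation among them, were chosen only after the result they concern was seen.

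Set against unstimulated wild-type cells, infected knockout cells had 20 of 33 lists called, 9 toward higher and 11 toward lower values, of which 13 held with an estimated correlation. In a fit of only the 6 libraries compared, 19 were called and 11 held. Glycolysis and hypoxia genes rose in 24 of 25 cases (24 adjusted over the list alone; list adjusted p = 6.08e-61), type 17 genes in 19 of 23 with 3 lower (19 and 3 adjusted over the list alone; list adjusted p = 1.02e-20) and cell cycle genes in 22 of 32 with 3 lower (22 and 3 adjusted over the list alone; list adjusted p = 3.67e-07). Interferon-gamma inducible GTPases and related genes fell in 17 of 22 cases and rose in 0 (17 lower and 1 higher adjusted over the list alone; list adjusted p = 1.95e-10). Myeloid inflammatory cytokines rose in 17 of 24 cases and fell in 3 (18 and 3 adjusted over the list alone; list adjusted p = 1.21e-11), while macrophage markers fell in 18 of 20 and rose in 2 (18 and 2 adjusted over the list alone; list adjusted p = 3.54e-13).

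The quality lists were not tested as groups. Of 4 sex-linked genes, Ddx3y fell after infection by 0.36 ± 0.11 (adjusted p = 0.034; 1 lower adjusted over the list alone), a call that ended without unstimulated replicate 2 or 3 or any of the 3 infected wild-type libraries (adjusted p = 0.0701, 0.139, 0.0769, 0.124 and 0.0987; range over 17 alternatives 0.00622 to 0.139). Uty was higher in the infected knockout by 0.88 ± 0.15 (adjusted p = 0.000209; 1 higher adjusted over the list alone). Of 26 tested genes on chromosome 1 around Il17a, 3 were higher and 6 lower after infection (4 and 7 adjusted over the list alone), and 7 higher and 4 lower in the knockout (6 and 3 adjusted over the list alone), among them Kcnq5 at 2.75 ± 0.32 and 2.18 ± 0.26 and Paqr8 at 2.30 ± 0.29 in the knockout. The lower count after infection was 2 without infected wild-type replicate 2 or 3 and 3 without unstimulated replicate 1 or 2. The lower count in the knockout was 1 without infected wild-type replicate 1 or 2 or knockout replicate 3, and 2 without unstimulated replicate 3. Mitochondrially encoded genes were not analysed here.

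With 10 splits of 6 libraries the splits are too few for a share under 0.05. The real split called 4584 genes for infection in wild-type cells, 5930 for the genotypes and 5799 for the secondary contrast in fits of those 6 libraries with edgeR, and 1 of 10 splits reached each. The highest other split called 0 genes in each, with 421, 225 and 450 genes at an unadjusted p under 0.05 against 5678, 6770 and 6628 in the real split. For lists the real values were 19 and 21 and the other splits gave 13 to 18 and 6 to 17, again with 1 of 10 splits as large. The number of lists called at the preset correlation thus set the real groups little apart from mixed ones. The other splits mix the groups unevenly and keep part of the group difference, so their list calls do not measure how many arise without it. Of the lists called in the same fits, 11 and 6 held in the real split with an estimated correlation, and 0 held in the other splits with camera, where at most 2 and 1 had an unadjusted p under 0.05. In a mixed split the group difference adds to the spread within each side. That lowers gene calls and list calls with an estimated correlation, so the values of 0 there were favoured in advance and do not set the real groups apart. For the secondary contrast, 8 to 17 lists were called in the other splits against 19 in the real split. For the 2156 genes changed in both main comparisons, 1 of 100 splits of the 9 libraries was as large, and the highest other gave 371. This argues against a random grouping of the libraries as the origin of a count of that size. Mixed splits call few genes in either comparison, so the splits do not test whether more genes are shared than independent lists of these sizes would share. Such lists would share 1617 genes, so a chance overlap of 2 long lists is not excluded for most of the count.

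Il17f in the knockout is the first pattern weighed. Il17f CPM in the knockout was 3.34 times the sum of Il17a and Il17f in infected wild-type libraries (788). At an unchanged output of both genes, that ratio argues against reads of Il17a assigned to Il17f. A larger share of type 17 cells would raise that output, and the ratio then cannot decide. The 25 other flanking genes had a median absolute log2 fold change of 0.34, and 85.7% of 11606 runs of as many neighbouring genes had one as large, which argues against a change shared by these 25 genes as a whole. Of them 10 passed, and Paqr8 (2.30) and Kcnq5 (2.18), which lie near Il17f, rose, so an effect of the altered Il17a allele on Il17f and single neighbours stays open. A larger share of type 17 cells may also contribute and cannot be told apart: Il17f rose by 4.56 and Ltb4r1, the highest of the 25 other tested members of the type 17 and gamma-delta lists, by 3.46, but members with a baseline in other cells would rise by less than the share, and regulation by the loss of IL-17A was not tested.

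Cell type markers that differ between the genotypes are the second pattern. A uniform loss of every type other than gamma-delta T cells would lower all their lists, but the neutrophil list had a median of 2.57, which argues against it as the whole account. Fewer alpha-beta T cells may explain the 8 of 10 tested alpha-beta T cell markers that were lower, but gamma-delta T cells also express such genes and the receptor genes that would tell them apart were not analysed here, so the explanations cannot be told apart. Isolation, mice and culture that differed between the groups, and the genotype itself, stay open as untested.

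Crystallin genes of the eye lens, chosen after their values were seen, are the third pattern. Of 16 listed, 14 had at least 30 reads in the unstimulated libraries and at least 80% of their reads there. Cryba4 (9.5%) and Crygn (64.7%) fell below that share. The 14 summed to 186, 49.5 and 426 CPM in the unstimulated libraries, and their higher values there follow from this choice. They summed to 2.03, 19.2 and 3.92 CPM in the infected wild-type libraries and 1.46, 1.14 and 1.95 in the infected knockout libraries. Of 10 other lens genes with at least 10 reads, 9 were highest in the unstimulated group, at up to 13.4 CPM for Tdrd7. RNA from eye lens carried into those libraries may thus be a source, although Tdrd7, Lenep and Hsf4 had over 2 CPM in every group. Whether isolation with magnetic beads removed lens cells and their RNA was not tested. Against reads shared between the gamma crystallin paralogs, 7 alpha or beta crystallins were among the 14 that met these limits. Whether 1 source kept its genes in a fixed ratio cannot be told: the 14 genes ranked the 3 libraries in 1 order, and their chi-square of 6.81 per degree of freedom, a test added after that order had been seen, lies below the 7.89 to 41.64 that genes at large gave between replicates. What brought the reads stays open, no biological explanation was tested, and Cryba4 differed, with 162 CPM in the knockout libraries.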
